A study of Mus musculus with 16 samples.

How the data were processed

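Gene expression was measured in the proximal colon of gnotobiotic mice, animals raised without microbes or with chosen species alone. The mice were NMRI males, an outbred stock, aged 12 to 14 weeks. The labels put the 16 arrays in 4 groups of 4 biological replicates: germ-free mice, mice carrying Eubacterium rectale, mice carrying Bacteroides thetaiotaomicron, and mice carrying both, here called co-colonized. Total RNA of homogenized tissue was purified on silica columns and copied into biotin-labelled cRNA, per the labels' protocols, so every cell layer present in the piece contributed.

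The deposited table held 1 intensity per probe set and array, never negative, for 45037 probe sets and no control probe sets. The probes of each set were summarised with PLIER, per the submitters' processing notes. The PLIER version, the background treatment and the normalization between arrays are not given in the sources used here. The values were on a linear scale, and dim probe sets came close to 0. For that reason 16 was added before log2 was taken, which understates the change of dim genes. Changes are therefore on the log2(intensity + 16) scale, and folds are derived from it. Array medians on this scale lay within 0.17 of each other, under the limit of 0.5 above which quantile normalization was to be applied, so the deposited normalization was kept. Intensities carry no count of molecules, and the number of arrays limits the precision.

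Probe sets were named through the platform annotation supplied with the values, which listed 35877 of them. Of these, 34945 had 1 gene and 932 had several, and the other 9160 are unnamed here. Entrez identifiers of 34741 probe sets with 1 gene were found in the mouse annotation of assembly GRCm38.p6, and 0 symbols changed. Each gene was represented by its brightest probe set, and by a probe set open to cross-hybridization only where it had no other, which was the case for 100 genes. This gave 18193 genes, of which 9010 had more than 1 probe set. The 10092 probe sets without a single gene were tested apart. One gene fixed for naming is not analysed here.

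Groups were compared with limma 3.58.1 in R 4.3.3. One linear model of 4 group means was fitted over all arrays, with moderated variances and 12 residual degrees of freedom. The contrasts were each colonized group against germ-free, the 3 comparisons among colonized groups, and the interaction, which asks whether the co-colonized change differs from the sum of the single-species changes on the log2 scale. P-values were two-sided and adjusted by Benjamini-Hochberg over all genes tested, with a call at 0.05. Errors of changes are standard errors of the fit, and errors of group means are standard deviations over 4 arrays. Genes whose groups of 4 did not overlap were counted, which chance alone gives for 2.86% of genes.

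There were 36 gene lists, with 1088 measured members, written before the data were examined. They covered signalling and proliferation (Wnt/beta-catenin pathway, stem and crypt base, cell cycle), defence (epithelial antimicrobial and mucosal defence, MHC class II and antigen presentation, interferon-stimulated genes, innate sensing and NF-kB), and immune cells (B and plasma cells, T and NK cells, macrophages with dendritic cells and neutrophils, mast cells). Lists for the rest of the colon wall were smooth muscle, enteric neurons and glia, fibroblasts and matrix, endothelium, absorptive colonocytes, goblet cells, enteroendocrine cells and tuft cells. Lists for metabolism and transport were short-chain fatty acid sensing, fatty acid oxidation and ketogenesis, the tricarboxylic acid cycle, oxidative phosphorylation, glycolysis, cholesterol biosynthesis, xenobiotic metabolism, glycosylation, tight junctions, and ion and water transport. Others were the unfolded protein response, immediate early and heat shock genes, the circadian clock, and genes of neighbouring tissues (exocrine pancreas, adipose tissue, blood, small intestine). Lists were tested with camera at a preset correlation of 0.01, two-sided and adjusted over the lists of a comparison. The same test with an estimated correlation, fry, and an exact permutation test of the list mean between groups of 4, whose smallest possible p is 0.0286, were run beside it. Members were also tested with adjustment over the list alone.

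Genes were named by a rule fixed before the data were examined. It took, per comparison of groups, the largest changes among genes past the threshold with no overlap between groups, or the 5 smallest p-values where none passed. It added up to 4 members of each list with the smallest p, and a fixed set of genes of microbial sensing and defence in comparisons against germ-free. Any gene named outside this rule was chosen after its values were seen. A Hox score was computed per array after the data were seen, as the mean centred log2 value of Hox paralogue group 13 minus that of groups 4 to 6.

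The fit was tested on simulated data with 200 changed genes among 18193 in each of 10 runs. For co-colonized against germ-free it recovered 51.9% of genes changed 1.5-fold, 87.9% of those changed 2-fold and 97.9% of those changed 4-fold, with 5.15% of calls false. For the interaction it recovered 24.9%, 65.7% and 94.7%. A list shifted by 0.3 was called in 10 of 10 runs, and an unshifted list in 1 run each for co-colonized against germ-free and for the interaction and in 0 runs for the other contrasts. Simulated genes varied independently, which members of a real list need not do.

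Alternatives fixed before the data were examined were other pseudocounts (1 and 64), only genes brighter than the median gene, quantile normalization, centring on the array median, an intensity trend, array weights, all probe sets, the mean of a gene's probe sets, a fit of only the groups compared, the replicate number as a block, a stricter threshold, a fold minimum, and leaving out each array. Omission of libraries that stood apart, the Hox score as a covariate, all colonized arrays together and the permutation of list means as a replacement for camera were added after the data were seen. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.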

Results

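The transcriptome of the proximal colon was compared between germ-free mice and mice carrying Eubacterium rectale, a butyrate-producing Firmicute, Bacteroides thetaiotaomicron, a polysaccharide-degrading Bacteroidete, or both species. There were 4 arrays in each of the 4 groups, and 18193 genes were tested. The design asks how the colon responds to each species alone and to both together. Median log2 intensities of the arrays ran from 6.49 to 6.66, and correlations between arrays across probe sets ran from 0.932 to 0.996.

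Several arrays stood apart from their groups. Hoxd13, a posterior Hox gene, read 11.3 in E. rectale replicate 1 and in co-colonized replicate 3, while the germ-free mean was 5.53 ± 0.50 (SD, n = 4). These libraries lay together at one end of the first principal component, which held 29.3% of the variance. A score of posterior minus anterior Hox genes averaged -0.98 ± 1.07 in germ-free, 0.49 ± 2.03 in E. rectale, -0.92 ± 1.07 in B. thetaiotaomicron and 1.41 ± 1.74 in co-colonized colons (SD, n = 4). Germ-free replicate 2 had the lowest median correlation with the other arrays (0.954) and set the second component, with 20.6% of the variance. Germ-free replicate 3 read 18.2 for the pancreatic protease gene Ctrb1, against 7.54 to 7.92 elsewhere. B. thetaiotaomicron replicate 4 had a T and NK cell marker mean of 1.46, against -0.24 to 0.048 in the rest of its group. The Hox genes and Ctrb1 were chosen after their values were seen.

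**Figure D1:**
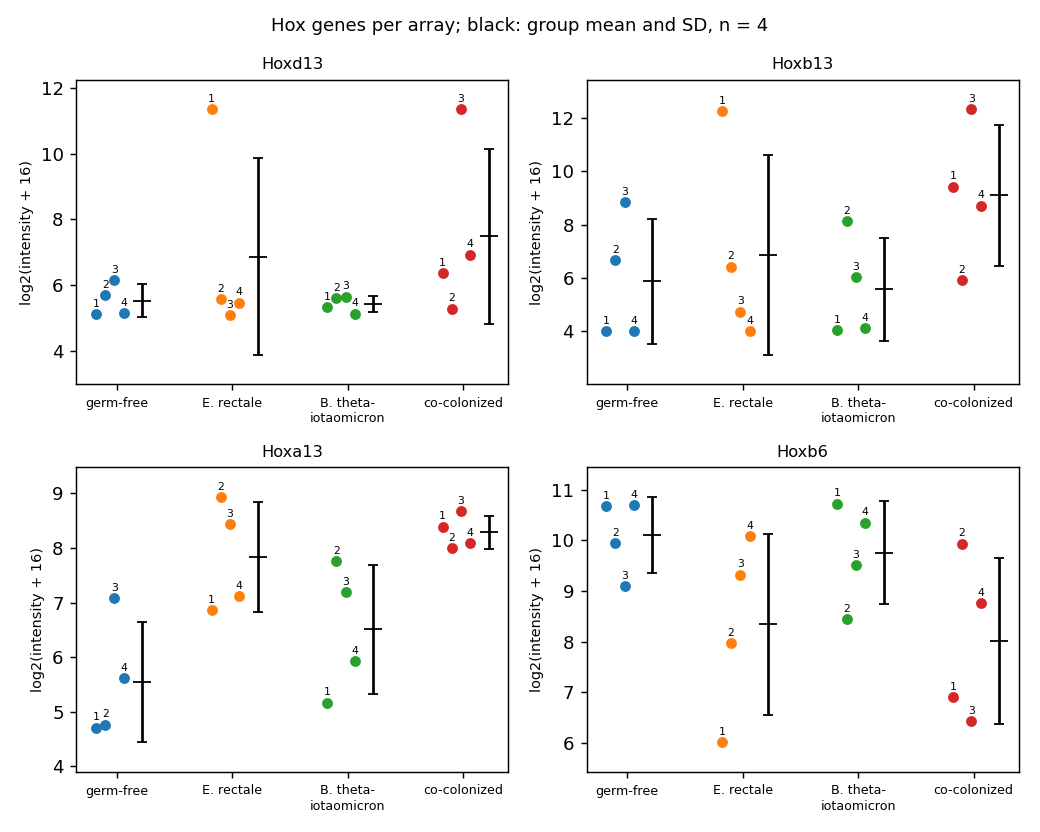
Log2(intensity + 16) of 4 Hox genes in each array, numbered by replicate, with the group mean and SD in black (n = 4). Hoxd13 reads 11.3 in E. rectale replicate 1 and in co-colonized replicate 3, where the anterior gene Hoxb6 is lowest in each of these groups.

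The comparison of co-colonized with germ-free colons held the single gene of that contrast past the threshold. Slc7a9, the light subunit of the epithelial transporter for cystine and dibasic amino acids, fell 2.20-fold, a log2 change of -1.13 (SE 0.14, limma adjusted p = 0.0149). Its mean was 9.56 ± 0.19 in germ-free, 9.39 ± 0.14 in E. rectale, 8.81 ± 0.14 in B. thetaiotaomicron and 8.43 ± 0.32 in co-colonized colons (SD, n = 4), and all 4 co-colonized values lay under all 4 germ-free values. Among list members, the gut hormone gene Cck changed by -3.42 (SE 0.61), and the apolipoprotein genes Apoc3 and Apoa1 by -1.51 (SE 0.22) and -2.49 (SE 0.55). The trehalase gene Treh changed by -0.75 (SE 0.20). Cck fell when adjusted over the enteroendocrine list alone, and Apoc3, Apoa1 and Treh over the small intestine list alone. Camera called neither list in this comparison. Of these 4 genes, 0 passed over all genes tested, where limma gave adjusted p = 0.0744 for Cck and 0.0546 for Apoc3.

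Genes of fibroblasts and matrix stood higher in co-colonized than in germ-free colons, by 0.34 on average over 31 members, of which 25 were higher. Adjusted over the list alone, 15 rose and 0 fell, and over all genes tested 0 passed. They included the collagen genes Col1a1 (0.72, SE 0.22) and Col1a2 (0.66, SE 0.17), the fibulin gene Fbln1 (1.26, SE 0.35) and Timp3 (0.74, SE 0.20), an inhibitor of matrix metalloproteinases. The camera adjusted p was 9.96e-08, with adjusted p = 0.844 with an estimated correlation, and an exact permutation test of the list mean gave p = 0.0286, the smallest it can give. Without germ-free replicate 2 the mean change was 0.22.

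Genes that build mucin and glycolipid sugar chains went both ways. Of 47 members, 6 rose and 2 fell when adjusted over the list alone, and 0 passed over all genes tested. B3gnt3, which extends mucin chains with N-acetylglucosamine, rose by 1.36 (SE 0.25), and B3galt5, which adds galactose, by 0.83 (SE 0.19). Fut8, Gcnt1, B3gnt2 and St3gal2 also rose in that test, while St6galnac1 (-0.77, SE 0.25) and Gal3st1 (-0.42, SE 0.13) fell. Without germ-free replicate 2, B3gnt3 passed over all genes at 1.02 (adjusted p = 0.0300). The list mean was 0.25 (camera adjusted p = 0.0151), with adjusted p = 0.844 with an estimated correlation and an exact permutation p of 0.0571. This call was lost with the Hox score as a covariate, at 0.21 (camera adjusted p = 0.117).

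Genes of adipose tissue were lower in co-colonized colons in all 12 members, by -1.12 on average. Adjusted over the list alone, 10 of the 12 fell and 0 passed over all genes tested, among them the hormone genes Lep (-1.21, SE 0.23) and Retn (-1.67, SE 0.54) and the fatty acid carrier Fabp4 (-1.21, SE 0.36). Lep passed over all genes without B. thetaiotaomicron replicate 4 (adjusted p = 0.0390), but it was dim, at 5.97 ± 0.28 in germ-free and 4.76 ± 0.21 in co-colonized colons (SD, n = 4). The camera adjusted p was 7.35e-06, with adjusted p = 0.844 with an estimated correlation and an exact permutation p of 0.0286. Within groups the adipose mean moved with the Hox score, by -0.35 (SE 0.05) per unit, and with the score as a covariate the call was lost, at -0.28 (camera adjusted p = 0.288). Smooth muscle (mean 0.22, and 0.38 with the covariate) and endothelium (mean 0.13) were also called by camera, each with adjusted p = 0.883 with an estimated correlation. Kcnmb1, a potassium channel subunit of smooth muscle, and Sox18, a vascular transcription factor, rose when adjusted over these lists alone, and 0 passed over all genes. The endothelial call was lost without germ-free replicate 1, at 0.093, and with the Hox score as a covariate, at 0.041. In lists that were not called, the axon and neuron genes Nefl (0.46, SE 0.11) and Stmn2 (0.42, SE 0.11) rose when adjusted over the list alone. The glial gene S100b (-0.73, SE 0.20) and the immunoproteasome subunit Psmb10 (-0.31, SE 0.08) fell in the same way.

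Over all genes 1 passed the threshold, while 3364 had an unadjusted p under 0.05, 1284 higher and 2080 lower. Groups did not overlap for 13.2% of genes, against 2.86% by chance. The Hox score averaged 1.41 in co-colonized and -0.98 in germ-free colons, so these counts do not tell colonization from the place sampled along the colon. The Slc7a9 call was kept in 22 of 29 alternatives and lost in 7, among them omission of germ-free replicate 4 (adjusted p = 0.0913) or co-colonized replicate 4 (0.0840) over a range of 0.000851 to 0.154. With array weights limma called 267 genes, and leaving out single arrays moved the count to 11 without germ-free replicate 3, 12 without E. rectale replicate 1, 4 without germ-free replicate 1 or 2, and 2 without B. thetaiotaomicron replicate 4 or co-colonized replicate 2.

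**Figure D2:**
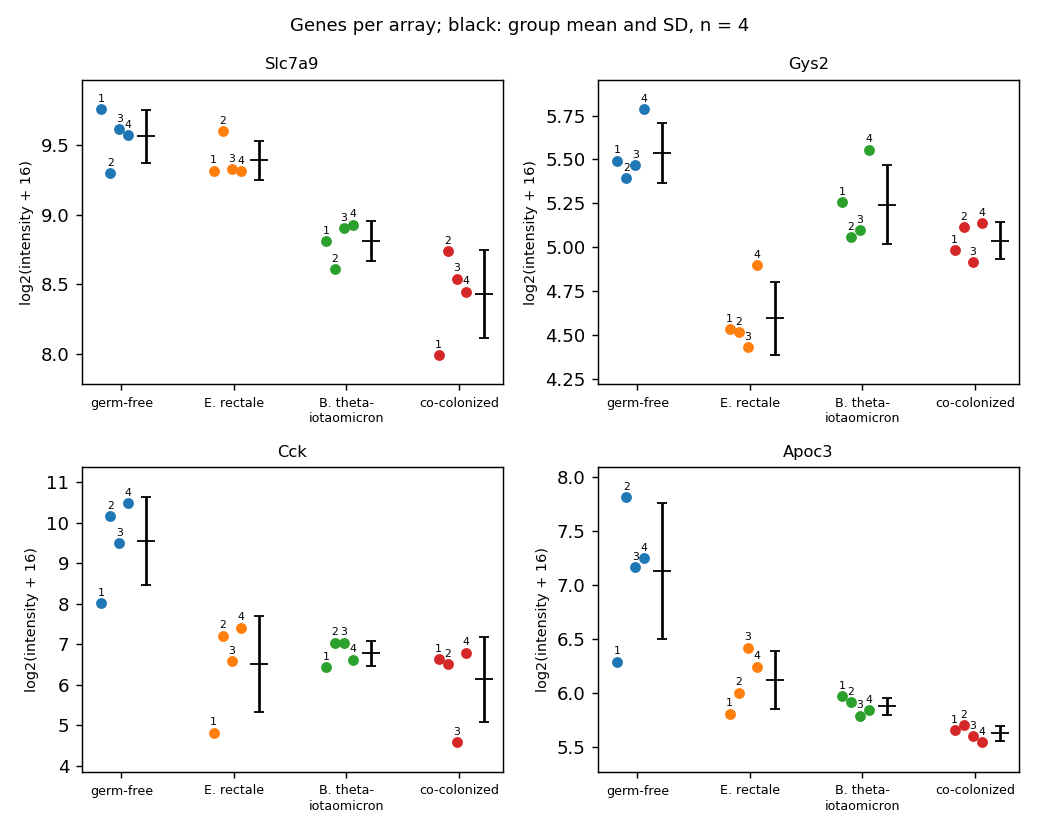
Log2(intensity + 16) of Slc7a9, Gys2, Cck and Apoc3 in each array, numbered by replicate, with the group mean and SD in black (n = 4). Slc7a9 means run from 9.56 in germ-free to 8.43 in co-colonized colons, and the highest Cck value of any colonized array, 7.41, lies under the lowest germ-free value, 8.03.

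Among the genes fixed for comparisons with germ-free, no member passed the threshold in any colonized group. Pigr, which carries immunoglobulin A across the epithelium, stood at 12.58 ± 0.91 in germ-free and 13.28 ± 0.11 in co-colonized colons (SD, n = 4), a difference of 0.70 (SE 0.30), although its other probe set had the opposite sign. Without germ-free replicate 2 it was 0.26. Slc16a1, a carrier of short-chain fatty acids and lactate, was 0.41 (SE 0.16) higher with no overlap, with its other probe set again opposite, and by 0.14 with the Hox score as a covariate. Gcg, which encodes proglucagon, was lower by log2 changes of -1.21 in E. rectale, -0.75 in B. thetaiotaomicron and -0.97 in co-colonized colons (SE 0.42 each). Without E. rectale replicate 1 the first was -0.72, and without co-colonized replicate 3 the last was -0.60. The antimicrobial lectin gene Reg3b averaged 12.30 ± 0.87 in germ-free, 9.91 ± 3.46 in E. rectale and 10.14 ± 1.99 in co-colonized colons (SD, n = 4), and its lowest value, 4.94, came from E. rectale replicate 1. Its relative Reg3g differed from germ-free by -2.50 (SE 1.35) in E. rectale and -1.78 (SE 1.35) in co-colonized colons. Without E. rectale replicate 1 the changes with E. rectale were -0.73 for Reg3b and -1.01 for Reg3g. In co-colonized colons they turned with the Hox score as a covariate, from -2.16 to 0.83 for Reg3b and from -1.78 to 1.29 for Reg3g. The ribonuclease gene Ang4 was 1.01 (SE 0.61) higher with E. rectale, and 0.54 higher without germ-free replicate 1. Muc2 and Retnlb, products of goblet cells, differed from germ-free by -0.074 to 0.091 in the colonized groups, and the signs for Muc2 with either species and for Retnlb with B. thetaiotaomicron changed under quantile normalization. Their germ-free means, 13.57 and 13.62, lay near the highest intensities of the arrays, where changes may be compressed. These small differences therefore do not show a lack of change. The remaining fixed genes in co-colonized colons were Slc5a8 (0.39), Fut2 (0.36), Pyy (0.09), Hcar2 (-0.26) and Ffar2 (-0.44), with limma adjusted p from 0.345 for Ffar2 to 0.846 for Pyy. Slc5a8 was 0.043 and Ffar2 -0.10 without co-colonized replicate 3, Fut2 was 0.10 without germ-free replicate 2, Pyy ran from 0.010 to 0.17 with single arrays left out, and Slc5a8 (-0.23) and Pyy (-0.18) turned with the Hox score as a covariate.

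Colonization with E. rectale alone gave 1 gene past the threshold. Gys2, the liver form of glycogen synthase, fell 1.92-fold, a log2 change of -0.94 (SE 0.13, limma adjusted p = 0.0382), from 5.53 ± 0.17 in germ-free to 4.59 ± 0.21 (SD, n = 4). Both means were dim, and the change ran from -1.82 with a pseudocount of 1 to -0.39 with a pseudocount of 64. Gys2 averaged 5.24 in B. thetaiotaomicron and 5.04 in co-colonized colons. The adipose list means had the same order of groups, at 0.69 in germ-free, 0.29 in B. thetaiotaomicron, -0.42 in co-colonized and -0.55 in E. rectale colons. Whether Gys2 and the adipose genes changed together was not tested. Cck was 8.23-fold lower (-3.04, SE 0.61) and fell when adjusted over the enteroendocrine list alone. Other members of that list were lower without passing, among them Gcg and Chga (-0.69, SE 0.26). The list mean was -0.49 (camera adjusted p = 0.0407), with adjusted p = 0.933 with an estimated correlation and an exact permutation p of 0.0286. Its call was lost without E. rectale replicate 1 (-0.35) or 2 (-0.51) or germ-free replicate 2 (-0.47) or 4 (-0.43). It was also lost with the Hox score as a covariate (-0.31, camera adjusted p = 0.401), without the 2 libraries with the highest Hoxd13 (-0.35) and without the 5 libraries that stood apart (-0.35). E. rectale replicate 1, one of those libraries, had an enteroendocrine mean of -0.61.

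All 12 adipose genes were lower with E. rectale, by -1.24 on average, and 10 fell when adjusted over the list alone, with 0 over all genes tested. Lep changed by -1.49 (SE 0.23), Adipoq, the adiponectin gene, by -1.97 (SE 0.72), and Adig by -0.81 (SE 0.17). The list mean was -0.73 with the Hox score as a covariate, and the call was kept. Camera gave adjusted p = 5.31e-08, with adjusted p = 0.933 with an estimated correlation and an exact permutation p of 0.0286. Interferon-stimulated genes were higher in 31 of 34 members, by 0.62 on average, and 0 passed over the list alone or over all genes. Ifih1, a sensor of viral RNA, differed by 0.55 (SE 0.19) and Stat2, a transcription factor of the interferon response, by 1.26 (SE 0.48). Camera gave adjusted p = 1.17e-08, with adjusted p = 0.933 with an estimated correlation and an exact permutation p of 0.314. Single arrays ranged from -0.82 in E. rectale replicate 1 to 1.32 in replicate 3, and the difference was 1.06 without the former and 0.35 without the latter. Within groups this list moved with the Hox score by -0.26 (SE 0.10) per unit, and with the score as a covariate the difference was 0.99.

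Camera also called smooth muscle (mean 0.13), glycosylation (mean 0.11) and antimicrobial defence for E. rectale, each with adjusted p = 0.933 with an estimated correlation and 0 members past the threshold over the list alone. Antimicrobial defence had a mean of -0.034, a median of 0.063 and an upward call, with Duoxa2, a maturation factor of the dual oxidase, at 1.12 (SE 0.30). These calls depended on single arrays. Smooth muscle was lost without E. rectale replicate 2 (0.081) or 4 (0.05) or germ-free replicate 4 (0.15), and read 0.27 without E. rectale replicate 1 and 0.07 without germ-free replicate 2. Glycosylation was lost without E. rectale replicate 1 (0.10) or 2 (0.07), germ-free replicate 1 (0.12) or 4 (0.13), or co-colonized replicate 2 or 3 (0.11), and read 0.034 without germ-free replicate 2, 0.17 without E. rectale replicate 3 and 0.18 without germ-free replicate 3. Antimicrobial defence was lost without E. rectale replicate 1 (-0.042) or 2 (-0.047) or germ-free replicate 1 (-0.016) or 4 (-0.00053), and read 0.041 without E. rectale replicate 3, -0.086 without E. rectale replicate 4, -0.12 without germ-free replicate 2 and 0.0021 without germ-free replicate 3. The glycosylation (0.088) and antimicrobial (-0.049) calls were lost with the Hox score as a covariate, where smooth muscle read 0.23. In lists that were not called, Apoc3 (-1.01, SE 0.22), S100b (-0.77, SE 0.20) and the globin gene Hbb-b2 (-0.44, SE 0.16) fell and Slc4a1, the anion exchanger of red cells, rose (0.51, SE 0.15) when adjusted over the list alone.

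At an unadjusted p under 0.05 there were 579 genes higher and 1805 lower with E. rectale, and groups did not overlap for 4.29% of genes against 2.86% by chance. The Gys2 call was lost in 19 of 28 alternatives, with adjusted p from 0.00176 to 0.257, among them omission of any germ-free array (0.0738 to 0.211), E. rectale replicate 1, 2 or 3 (0.112 to 0.255), B. thetaiotaomicron replicate 1 (0.0876) or 3 (0.0652), or any co-colonized array (0.0610 to 0.0848). The number of genes called was 2 without B. thetaiotaomicron replicate 2 and 4 without B. thetaiotaomicron replicate 4, and Lep was among them, at adjusted p = 0.0382 and 0.00632.

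Colonization with B. thetaiotaomicron alone gave 0 genes past the limma threshold and 796 with an unadjusted p under 0.05, 409 higher and 387 lower. The smallest p belonged to Apoc3, at 5.88 ± 0.08 against 7.13 ± 0.63 in germ-free colons (SD, n = 4), a difference of -1.25 (SE 0.22). Without germ-free replicate 1 it passed over all genes, at -1.53 (adjusted p = 0.00173). Apoc3 fell when adjusted over the small intestine list alone, and Cck (-2.77, SE 0.61) over the enteroendocrine list alone, which camera did not call here. Slc7a9 (-0.75, SE 0.14), the cytoskeletal linker gene Plec (-0.39, SE 0.09) and Tfrc, the transferrin receptor (-0.77, SE 0.18), followed in rank and did not pass, and for Plec and Tfrc 1 of 2 other probe sets had the opposite sign. Groups did not overlap for 3.79% of genes, against 2.86% by chance.

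Camera called 7 lists for B. thetaiotaomicron, 3 without germ-free replicate 1, 13 without germ-free replicate 2, 4 without germ-free replicate 4 and 11 without B. thetaiotaomicron replicate 1 or 4. Genes abundant in the small intestine were lower in 19 of 21 members, with a mean of -0.29 (camera adjusted p = 0.00117, with adjusted p = 0.493 with an estimated correlation). Apoa1, an apolipoprotein of high-density lipoprotein, differed by -1.73 (SE 0.55) in this list. Genes of fibroblasts and matrix were higher in 26 of 31 members (mean 0.19, and 0.076 without germ-free replicate 2), and this list and the other 5 called had adjusted p = 0.972 with an estimated correlation. Genes of cholesterol biosynthesis had a mean of -0.14, and Acaca, acetyl-CoA carboxylase, fell by 0.48 when adjusted over the list alone, with 0 members past the threshold over all genes. This call was lost without B. thetaiotaomicron replicate 4 (-0.08) or germ-free replicate 1 (-0.12). All 17 exocrine pancreas genes were lower, by -1.18 on average, and the call was lost without germ-free replicate 3, at -0.038. Adipose tissue (mean -0.41) was lost without B. thetaiotaomicron replicate 2 (-0.15) or 3 (-0.33) or germ-free replicate 1 (-0.35) or 4 (-0.30), and read -0.67 without B. thetaiotaomicron replicate 4. Macrophage genes (mean 0.17) were lost without B. thetaiotaomicron replicate 4 (-0.021) or germ-free replicate 1 (0.14) or 4 (0.19), and read 0.26, 0.093 and 0.28 without B. thetaiotaomicron replicate 2 and germ-free replicates 2 and 3. Smooth muscle (mean 0.15) was lost without B. thetaiotaomicron replicate 2 (0.086) or 3 (0.10), germ-free replicate 1 or 4 (0.16), or co-colonized replicate 2 or E. rectale replicate 3 (0.15), and read 0.082 without germ-free replicate 2.

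Adding E. rectale to B. thetaiotaomicron was examined by comparing co-colonized with B. thetaiotaomicron colons. Limma called 0 genes, with 974 at an unadjusted p under 0.05, of which 277 were higher and 697 lower, and groups did not overlap for 7.26% of genes against 2.86% by chance. Genes of cholesterol biosynthesis were higher in 25 of 29 members, by 0.27 on average, with Dhcr7 (0.35, SE 0.11) and Mvk (0.47, SE 0.17) leading. Camera gave adjusted p = 5.31e-10, with adjusted p = 0.409 with an estimated correlation and 0 members past the threshold over the list alone or over all genes. The mean was 0.18 without co-colonized replicate 3, and with the Hox score as a covariate the call was lost, at 0.056. Ion and water transport genes had a mean of 0.30 and a median of 0.049, also with adjusted p = 0.409 with an estimated correlation, and Aqp8, a colonic water channel, differed by 2.73 (SE 1.14). The ion and water transport call was lost with the Hox score as a covariate, at -0.0010. Adipose genes were lower in all 12 members (mean -0.71, and -0.45 without B. thetaiotaomicron replicate 4 or -0.37 without co-colonized replicate 3), with adjusted p = 0.822 with an estimated correlation. Lep fell by 0.78 when adjusted over the list alone and 0 passed over all genes tested. The adipose mean was 0.11 with the Hox score as a covariate, and the call was lost. The 5 genes with the smallest p, none past the threshold, were Ctla2b (-0.58), Dtnb (-0.38), Id2 (-0.47), a regulator of cell differentiation, Igk-V21 (1.27), an immunoglobulin light chain segment, and Il1f5 (0.36), whose other probe set had the opposite sign.

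The other lists called in that comparison were fibroblasts and matrix (mean 0.14), T and NK cells (-0.44), mast cells (0.20), smooth muscle (0.075) and fatty acid oxidation (-0.21), each with adjusted p = 0.822 with an estimated correlation, and antimicrobial defence (0.072), with adjusted p = 0.673 with an estimated correlation. No member of these 6 lists passed over the list alone. The T and NK cell difference was -0.047 without B. thetaiotaomicron replicate 4, where the call was lost. The mast cell difference was -0.017 without co-colonized replicate 3 and 0.19 without B. thetaiotaomicron replicate 1, and neither was called. Fatty acid oxidation genes, led by Pdk4 (-0.89, SE 0.28) and Angptl4 (-1.20, SE 0.43), lost their call without B. thetaiotaomicron replicate 1 (-0.19) or 4 (-0.16), co-colonized replicate 1 (-0.18) or 3 (-0.13), or E. rectale replicate 3 or germ-free replicate 2 (-0.21). Smooth muscle lost its call without B. thetaiotaomicron replicate 1 (0.023) or 4 (0.021) or co-colonized replicate 1 (0.023), 2 (0.064) or 4 (0.03), and read 0.13, 0.12 and 0.18 without B. thetaiotaomicron replicates 2 and 3 and co-colonized replicate 3. Antimicrobial defence lost its call without B. thetaiotaomicron replicate 1 (0.045) or co-colonized replicate 3 (0.031), and read 0.11 without B. thetaiotaomicron replicate 4 and 0.13 without co-colonized replicate 1. With the Hox score as a covariate the calls of T and NK cells (-0.37), mast cells (-0.10) and antimicrobial defence (0.048) were lost, fatty acid oxidation read 0.057 (camera adjusted p = 0.0359), and smooth muscle read 0.23.

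Adding B. thetaiotaomicron to E. rectale was examined by comparing co-colonized with E. rectale colons. Slc7a9 again had the smallest p, at 8.43 ± 0.32 against 9.39 ± 0.14 (SD, n = 4), a difference of -0.96 (SE 0.14, limma adjusted p = 0.110) that did not pass. The chloride channel regulator gene Clca4b followed (-1.09, SE 0.22) and fell when adjusted over the goblet cell list alone. So did the pancreatic lipase gene Pnliprp2 (-3.28, SE 1.00) and the colipase gene Clps (-1.14, SE 0.32) over the pancreas list alone, with 0 over all genes tested. Camera called neither the goblet cell nor the pancreas list in this comparison. Catsperg2 (-0.77), Dnaic1 (0.45) and Septin4 (0.47) completed the 5 smallest p-values. Limma called 0 genes, with 689 at an unadjusted p under 0.05, and groups did not overlap for 2.61% of genes against 2.86% by chance. Slc7a9 passed in this comparison after quantile normalization (-1.01, adjusted p = 0.0153), after centring on array medians (-0.97, adjusted p = 0.0381), and without co-colonized replicate 2 (-1.06, adjusted p = 0.04997).

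Genes of fibroblasts and matrix were higher in co-colonized than in E. rectale colons in all 31 members, by 0.26 on average, led by Mfap4 (0.51, SE 0.16) and Ogn (0.39, SE 0.13). Camera gave adjusted p = 4.39e-11, with adjusted p = 0.675 with an estimated correlation and an exact permutation p of 0.0286, and 0 members passed over the list alone or over all genes. Interferon-stimulated genes were lower in 32 of 34 members, by -0.64 on average, with Oasl1 at -0.88 (SE 0.33). Camera gave adjusted p = 1.07e-13, with adjusted p = 0.958 with an estimated correlation, and the exact permutation p was above 0.05. Over arrays the list mean differed by -0.64 (SE 0.45), under 2 SE from 0. The difference was -1.08 without E. rectale replicate 1, -0.37 without E. rectale replicate 3 and -0.41 with the Hox score as a covariate. The small intestine list (mean -0.15), with adjusted p = 0.675 with an estimated correlation, was lost without co-colonized replicate 1 (-0.14) or E. rectale replicate 2 (-0.045) or 3 (-0.13), and read -0.029, -0.33 and -0.08 without co-colonized replicate 3 and E. rectale replicates 1 and 4. Endothelium (0.17), macrophages (0.16) and cell cycle (-0.073) were called with adjusted p = 0.958 with an estimated correlation. Endothelium was lost without E. rectale replicate 3 (0.077) and read 0.26 without replicate 1. Cell cycle was lost without co-colonized replicate 2 (-0.047) or 3 (-0.033) and read -0.14 without replicate 1. Macrophage genes were lost without co-colonized replicate 2 (0.12) or 3 (0.11), E. rectale replicate 1 (0.17) or 3 (0.085), or germ-free replicate 2 (0.16). The small intestine (-0.043) and macrophage (0.15) calls were lost with the Hox score as a covariate.

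The mono-associated groups were compared with each other, B. thetaiotaomicron minus E. rectale. Interferon-stimulated genes were lower with B. thetaiotaomicron in 32 of 34 members, by -0.76 on average. Oas1a (-1.08, SE 0.27) and Oasl1 (-1.26, SE 0.33), of the antiviral oligoadenylate synthetase family, and Ifih1 (-0.64, SE 0.19) fell when adjusted over the list alone, with 0 over all genes tested. Camera gave adjusted p = 1.36e-15, with adjusted p = 0.556 with an estimated correlation and an exact permutation p of 0.314, and the difference was -1.20 without E. rectale replicate 1 and -0.49 without E. rectale replicate 3. Cholesterol biosynthesis had a mean of -0.24 (-0.11 with the Hox score as a covariate), also with adjusted p = 0.556 with an estimated correlation. Adipose genes were higher in all 12 members (mean 0.84, 0.56 without E. rectale replicate 1, and 0.34 with the Hox score as a covariate), with adjusted p = 0.898 with an estimated correlation. Lep rose by 1.06 (SE 0.23) when adjusted over the list alone. Duoxa2 (-1.21, SE 0.30), Clca4b (-0.90, SE 0.22) and Pnliprp2 (-3.92, SE 1.00) fell in the same way in the antimicrobial, goblet cell and pancreas lists, of which goblet cells were not called.

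Limma called 0 genes between the mono-associated groups, with 1654 at an unadjusted p under 0.05, 1223 higher and 431 lower, and groups did not overlap for 5.58% of genes against 2.86% by chance. Gys2 (0.65, SE 0.13), Mov10 (-0.53, SE 0.11), an RNA helicase, the transcription factor gene Klf15 (0.86, SE 0.18), Igf1os (-0.54, SE 0.12) and Lep had the smallest p. Igf1os and Lep were dim, averaging 4.09 and 5.53 with B. thetaiotaomicron and 4.63 and 4.47 with E. rectale. Camera also called T and NK cells (0.53), macrophages (0.34), enteric neurons and glia (0.17), fatty acid oxidation (0.23) and exocrine pancreas (-0.59), which like adipose tissue had adjusted p = 0.898 with an estimated correlation. Both immune lists were lost without B. thetaiotaomicron replicate 4, at 0.14 each. Enteric neurons and glia were lost without B. thetaiotaomicron replicate 2 (0.18) or 3 (0.15) or E. rectale replicate 1 (0.17) or 3 (0.12), and fatty acid oxidation without B. thetaiotaomicron replicate 1 (0.21) or 4 (0.19), E. rectale replicate 1 (0.12) or co-colonized replicate 1 (0.23). Antimicrobial defence had a mean of 0.0025, a median of -0.068 and a downward call, and small intestine a mean of -0.0055 and a median of -0.094, both with adjusted p = 0.556 with an estimated correlation. The former was lost without B. thetaiotaomicron replicate 1 (0.029) or E. rectale replicate 1 (0.011) or 2 (0.016), and the latter without E. rectale replicate 2 (0.096). Without other single arrays of these groups the antimicrobial mean ran from -0.072 without E. rectale replicate 3 to 0.055 without E. rectale replicate 4. The small intestine mean ran from -0.19 without E. rectale replicate 1 to 0.061 without E. rectale replicate 4, and read -0.16 with the Hox score as a covariate. With that covariate the calls of enteric neurons and glia (0.13), fatty acid oxidation (0.071), exocrine pancreas (-0.085) and antimicrobial defence (0.017) were lost.

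**Figure D3:**
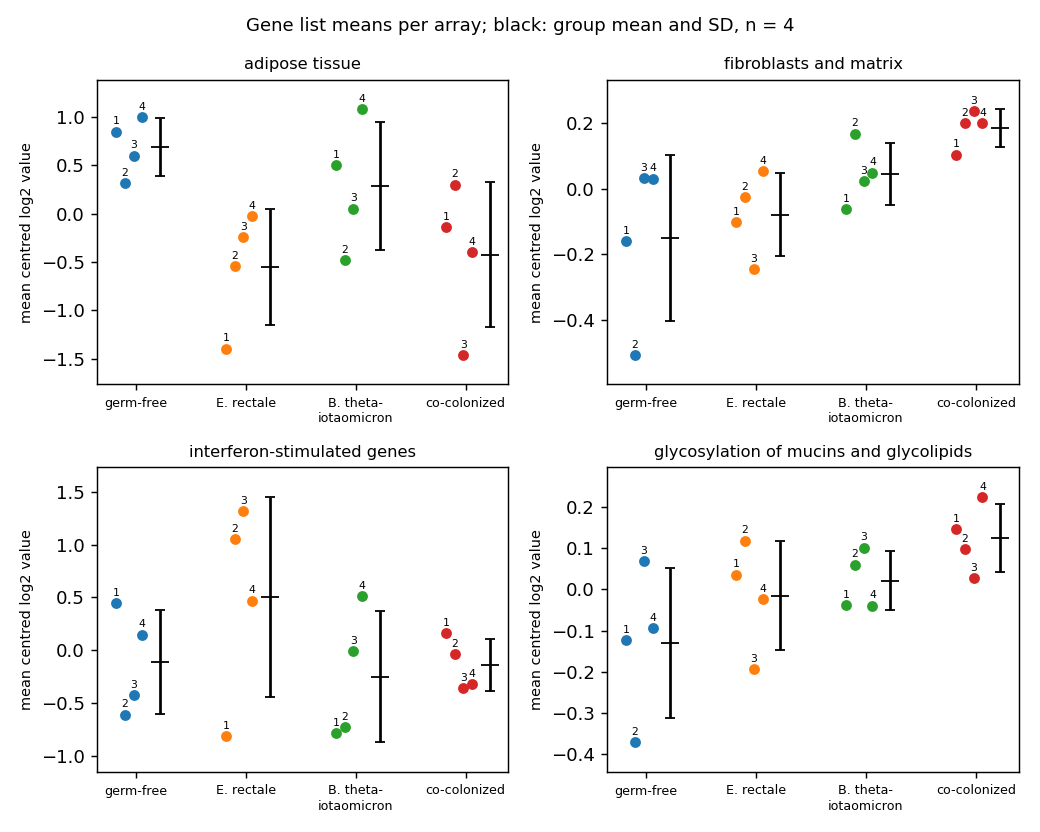
Mean centred log2 value of 4 gene lists in each array, numbered by replicate, with the group mean and SD in black (n = 4). Fibroblast and matrix genes average -0.15 in germ-free and 0.19 in co-colonized colons, and interferon-stimulated genes spread from -0.82 to 1.32 within the E. rectale group.

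The interaction asked whether the co-colonized change differed from the sum of the single-species changes. Limma called 0 genes, with 246 at an unadjusted p under 0.05. The 5 smallest p-values, none past the threshold, were those of Pou5f1 (0.44), the tyrosine kinase gene Fer (-1.36), Gys2 (0.74), Idi2 (-1.30) and Morc2b (0.55). Camera called 4 lists (7 without B. thetaiotaomicron replicate 2 or 4, and 2 without co-colonized replicate 2), each with adjusted p = 0.948 with an estimated correlation and 0 members past the threshold over the list alone. They were interferon-stimulated genes (-0.50), adipose tissue (0.53), cholesterol biosynthesis (0.18) and cell cycle (-0.078). The interferon call was lost without E. rectale replicate 3 (-0.23), and its mean was -0.94, -0.32 and -0.25 without E. rectale replicates 1 and 2 and B. thetaiotaomicron replicate 4. The adipose call was lost without B. thetaiotaomicron replicate 2 (0.28) or 3 (0.45), E. rectale replicate 1 (0.25) or co-colonized replicate 2 (0.29), and its mean was 0.88 without co-colonized replicate 3. The cholesterol call was lost without B. thetaiotaomicron replicate 4 (0.12), co-colonized replicate 3 (0.084) or E. rectale replicate 4 (0.14), and its mean was 0.12 without E. rectale replicate 3. With the Hox score as a covariate the cholesterol call was lost, at 0.099, and the interferon and adipose means were -0.28 and 0.84. The cell cycle call was lost without germ-free replicate 3 (-0.025), E. rectale replicate 1 (-0.069) or 3 (-0.09), B. thetaiotaomicron replicate 1 (-0.061) or 3 (-0.027), or co-colonized replicate 2 (-0.052), 3 (-0.038) or 4 (-0.073). Its mean was -0.12, -0.14 and -0.15 without germ-free replicate 1, B. thetaiotaomicron replicate 4 and co-colonized replicate 1.

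The changes against germ-free shared their control arrays, so chance alone ties them together. Across genes, which are not independent replicates, the changes with E. rectale and in co-colonized colons correlated at 0.827. Simulated arrays without group differences, controls included, gave 0.497. Simulated genes varied independently, which real genes need not do, so this value holds the tie from shared controls but not all of chance. With separate germ-free arrays for each contrast the real changes correlated at 0.460, an observed value without that tie. Without E. rectale replicate 1 and co-colonized replicate 3 the correlation with shared controls was 0.753 (simulated 0.430, separate controls 0.403). The covariance of these changes over all arrays was 0.0602 against a simulated 0.0191. For B. thetaiotaomicron and co-colonized colons the correlation was 0.673 (simulated 0.5002, separate controls 0.240) and the covariance 0.0360 (simulated 0.0192). For the single species it was 0.501 (simulated 0.499, separate controls 0.0753), with a covariance of 0.0240 (simulated 0.0192). Without the same libraries the single-species correlation was 0.541 (simulated 0.463, separate controls 0.124), with a covariance of 0.0279 (simulated 0.0145). That of B. thetaiotaomicron and co-colonized colons was then 0.720 (simulated 0.462, separate controls 0.250). At an unadjusted p under 0.05, 312 genes were higher and 1138 lower in both E. rectale and co-colonized colons, where independent lists would share 40.9 and 206 and the simulation gave 203 in the same direction. The number called in both was 0.

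Of the 36 lists, 18 were called by camera in no comparison. The smallest adjusted p any of them reached was 0.0563 for MHC class II and antigen presentation, 0.0786 for tuft cells, 0.0812 for tight junctions, 0.0938 for B and plasma cells, 0.103 for goblet cells and for the unfolded protein response, 0.111 for immediate early and heat shock genes, and 0.161 for stem and crypt base. It was 0.181 for absorptive colonocytes, 0.2 for innate sensing and NF-kB, 0.282 for glycolysis, 0.309 for xenobiotic metabolism, 0.351 for oxidative phosphorylation, 0.361 for short-chain fatty acid sensing and for the tricarboxylic acid cycle, 0.527 for the circadian clock and for blood, and 0.607 for the Wnt/beta-catenin pathway. With an estimated correlation or fry, 0 of the 36 lists were called in any comparison, and at least as many camera calls came from 25 to 31 of 35 splits of the arrays of 2 groups, the real one included, and from 95 of 100 for the interaction.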

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

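The comparison of fibroblast with neuron genes, the test on macrophages alone and the test of sampling position as the whole cause for adipose genes were chosen after their results were seen, and the use of the Hox score as a covariate was chosen after the Hox values were seen.

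Arrays far from the other 3 of their group were found for 13 of 156 groups of values, 8.33%, where chance gives about 1 in 20. In B. thetaiotaomicron replicate 4 the means of T and NK cells (1.46, others -0.24 to 0.048), macrophages (0.76, others -0.088 to 0.017) and endothelium (0.39, others -0.087 to -0.014) were all high. Germ-free replicate 2 was low for antimicrobial defence (-0.25, others 0.06 to 0.11) and for innate sensing (-0.15, others 0.014 to 0.038). Germ-free replicate 3 was high for exocrine pancreas, at 4.12 against -0.68 to -0.17. E. rectale replicate 1 was low for xenobiotic metabolism (-0.75, others 0.0014 to 0.13), and co-colonized replicate 3 was high for mast cells (0.81, others -0.098 to -0.032). E. rectale replicate 3 was low for glycolysis (-0.16, others -0.0078 to 0.014). Circadian clock genes were low in B. thetaiotaomicron replicate 2 (-0.12, others 0.059 to 0.082) and in co-colonized replicate 1 (-0.24, others 0.0044 to 0.047). Blood genes were high in B. thetaiotaomicron replicate 1, at 0.20 against -0.082 to -0.037. Slc7a9 was 9.60 in E. rectale replicate 2, above the other values of that group at 9.31 to 9.33.

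Camera called 4 lists for the interaction, which asks whether the effect of adding E. rectale differed with and without B. thetaiotaomicron. At least as many lists were called in 95 of 100 drawn splits of the arrays, the real one included, so chance cannot be excluded. The list means were -0.50 for interferon-stimulated genes, 0.53 for adipose tissue, 0.18 for cholesterol biosynthesis and -0.078 for cell cycle, each with adjusted p = 0.948 with an estimated correlation. Among 10092 probe sets without a single gene name, limma called 2 between co-colonized and germ-free colons, with log2 changes of -1.63 and -0.85, and 1733 had an unadjusted p under 0.05.

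Fibroblast and matrix genes were 0.34 (SE 0.11) higher in co-colonized than in germ-free colons. A shift in the place sampled along the colon would shrink that difference once the Hox score is a covariate. The difference stayed at 0.31 (SE 0.13), with a slope of 0.012 (SE 0.03) on the score. As far as the score follows position, this argues against that explanation as the whole cause. A larger share of all non-epithelial tissue would raise neuron and glia genes alike. The fibroblast mean minus the neuron and glia mean was 0.36 (SE 0.12) higher, but much of this came from arrays that stood apart. Neuron and glia genes read -0.25 in co-colonized replicate 3, against 0.016 to 0.098 in the rest of its group. Fibroblast genes read -0.51 in germ-free replicate 2, against -0.16 to 0.033. A larger share of non-epithelial tissue therefore stays open. Smooth muscle was 0.22 (SE 0.15) higher, so a thicker share of muscle with its connective tissue stays open, as does the low germ-free replicate 2, without which the list difference was 0.22. An increase of matrix gene expression with both species is a hypothesis, found and tested on the same arrays.

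Interferon-stimulated genes were -0.64 (SE 0.45) apart between co-colonized and E. rectale colons. That is under 2 SE from 0, so chance differences between animals stay open. With the Hox score as a covariate the difference was -0.41 (SE 0.37), with a slope of -0.26 (SE 0.10) per unit of score, so sampling position cannot be told apart from colonization because the score differs between the groups. Leaving out E. rectale replicate 3 gave -0.37 (SE 0.45), which leaves 1 deviating library open as well. More T and NK cells in the E. rectale samples would give a positive difference of their own. It was -0.097 (SE 0.31), an error too wide to exclude a partial share. That error was pooled over all groups, with B. thetaiotaomicron replicate 4 at 1.46. The list averaged -0.24 ± 0.17 in E. rectale and -0.15 ± 0.11 in co-colonized colons (SD, n = 4), which argues against more T and NK cells as the whole source. Macrophages, dendritic cells and neutrophils gave -0.16 (SE 0.18), which lies more than 2 of its SE below a positive difference as large as the interferon one and argues against more of these cells as the source. Damping of an interferon response to E. rectale by B. thetaiotaomicron stays among the open explanations, untested apart from these.

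Adipose genes were lower by -1.24 (SE 0.43) in E. rectale than in germ-free colons. Within groups the 12 genes rose and fell together, with a median pairwise correlation of 0.822, as a variable amount of attached fat tissue would give. The highest of 1000 random lists of 12 genes gave 0.352, but random genes were not chosen as markers of 1 tissue. Altered fat gene expression or a shift in sampling position could move these genes together too, so the correlation does not decide between them. The members with the highest intensities, which do not rank abundance between probe sets, were Car3, at 12.19 ± 0.52 in germ-free and 10.42 ± 1.20 in E. rectale colons, and Fabp4, at 12.14 ± 0.33 and 10.98 ± 0.52 (SD, n = 4), and how many of the 12 the colon wall itself expresses was not tested. With the Hox score as a covariate the difference was -0.73 (SE 0.21), over 2 SE from 0. How exactly the score measures position is unknown, and an inexact score removes only part of its effect. The remainder therefore does not decide whether sampling position is the whole cause. The slope was -0.35 (SE 0.05) per unit of score, so position cannot be told apart from colonization for the part the score removed. Less mesenteric fat or altered fat gene expression in mice carrying E. rectale is a biological explanation that these arrays leave untested.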

How the results depend on the processing

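The omission of libraries that stood apart, the Hox score as a covariate, the correlation of changes without 2 libraries and the permutation of list means as a replacement for camera were chosen after the data were seen. Under an intensity trend and a minimum fold of 1.5 the counts of genes stayed within 1.5 times the values reported. Of 7147 gene values under alternatives, 7049 kept their direction and side of the threshold, 26 no longer passed, 23 newly passed and 49 changed sign, 48 of these with an unadjusted p of 0.05 or more in both settings. Of 1450 list values, 1166 kept their call, 278 lost it and in 6 camera's direction turned, while the list mean changed sign in 25. The fibroblast and interferon calls between 2 groups were lost with the estimated correlation and with fry. They were also lost with exact permutation of the list means adjusted over the lists, which could hardly call any list. They were kept under the other alternatives run. The cause of the changes below was not tested, except that omissions and fits of fewer arrays have fewer degrees of freedom and a stricter threshold passes fewer genes.

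The count of genes called between co-colonized and germ-free colons, 1 in the report, was 3 with a pseudocount of 1 or 64, 267 with array weights, 2 over all probe sets, 6 without the 5 libraries that stood apart, and 0 in a fit of only the groups compared, with the replicate number as a block, at an adjusted p under 0.01, without the 2 libraries with the highest Hoxd13, and with the Hox score as a covariate. For E. rectale against germ-free, 1 in the report, it was 2 with arrays centred on their medians, 4 without 5 libraries, and 0 with a pseudocount of 64, brighter genes, array weights, all probe sets, only the groups compared, an adjusted p under 0.01, without 2 libraries, and with the Hox score. Where the report gives 0, co-colonized against E. rectale gave 1 after quantile normalization, after centring and with the Hox score, and without 5 libraries B. thetaiotaomicron gave 1 against germ-free and 17 against E. rectale. With single arrays left out, counts ran from 0 to 4 for E. rectale against germ-free, 0 to 1 for B. thetaiotaomicron against germ-free, 0 to 12 for co-colonized against germ-free, 0 to 1 for co-colonized against E. rectale, and 0 to 0 elsewhere.

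The number of lists called fell to 0 in every comparison with an estimated correlation and with fry. It was also 0 with exact permutation of list means, which was not run for the interaction. The smallest possible p of 0.0286, adjusted over 36 lists, passes only if many lists reach it together, so that 0 was nearly fixed in advance. Otherwise the number of lists called was 2 with brighter genes, 11 with the mean of probe sets and 13 without 5 libraries for B. thetaiotaomicron against germ-free (7 in the report). It was 3 with brighter genes, 11 with array weights, 12 with the mean of probe sets and 13 without 5 libraries for co-colonized against germ-free (5), and 3 without 2 libraries and 3 with the Hox score for E. rectale against germ-free (6). It was 16 with brighter genes and 6 without 5 libraries for B. thetaiotaomicron against E. rectale (10), 10 with the mean of probe sets and 11 with the Hox score for co-colonized against E. rectale (6), and 8 with the Hox score for the interaction (4). With single arrays left out it ran from 2 to 12 for E. rectale, 3 to 13 for B. thetaiotaomicron and 5 to 12 for co-colonized colons against germ-free, 6 to 15 for co-colonized against B. thetaiotaomicron, 4 to 9 for co-colonized against E. rectale, 8 to 13 between single species and 2 to 7 for the interaction. Among lists against germ-free, brighter genes ended the calls of glycosylation and endothelium in co-colonized colons, of antimicrobial defence, enteroendocrine cells and glycosylation with E. rectale, and of small intestine, adipose tissue, pancreas, smooth muscle and macrophages with B. thetaiotaomicron.

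Slc7a9 between co-colonized and germ-free colons ranged from -1.30 to -0.99, with adjusted p from 0.000851 to 0.154, and Gys2 between E. rectale and germ-free from -1.82 to -0.39, with adjusted p from 0.00176 to 0.257. With the replicate number as a block the adjusted p of Slc7a9 was 0.0758 and 3015 genes had an unadjusted p under 0.05. Equal replicate numbers did not pair the arrays: of 24 pairs, 8 correlated above 0.1, over a range of -0.40 to 0.42 with a median of -0.13.

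Changes of sign against germ-free were as follows. After quantile normalization Muc2 was 0.023 with E. rectale and 0.094 with B. thetaiotaomicron, and Retnlb 0.16 with B. thetaiotaomicron. With array weights Muc2 was 0.017 with E. rectale, and with B. thetaiotaomicron Ffar2 was 0.053, Ang4 0.28, Retnlb 0.010 and Pyy 0.050. With the mean of probe sets Slc16a1 was -0.049 and Ffar2 0.074 with B. thetaiotaomicron. Without 2 libraries Slc5a8 was -0.058 with E. rectale and Muc2 0.018 in co-colonized colons. Without 5 libraries Slc5a8 was -0.18 and Fut2 -0.070 with E. rectale, Slc5a8 was -0.078 and Muc2 0.0062 in co-colonized colons, and with B. thetaiotaomicron Ffar2 was 0.033, Ang4 0.60, Retnlb 0.019, Pyy 0.19, Rnase1 0.038 and the pancreas list 0.15. With the Hox score Slc5a8 was -0.095, Muc2 0.031 and Pyy -0.018 with E. rectale, and in co-colonized colons Slc5a8 was -0.23, Reg3b 0.83, Reg3g 1.29, Muc2 0.026 and Pyy -0.18. With single arrays left out, the change with B. thetaiotaomicron ran for Reg3g from -0.75 to 0.46 (0.33 without germ-free replicate 1, 0.46 without B. thetaiotaomicron replicate 2), for Ffar2 from -0.14 to 0.046 (the latter without germ-free replicate 2), and for Ang4 from -0.49 to 0.75 (0.085, 0.36 and 0.75 without germ-free replicates 2 and 3 and B. thetaiotaomicron replicate 1). It ran for Pyy from -0.29 to 0.059 (the latter without B. thetaiotaomicron replicate 1), for Slc16a1 from -0.047 to 0.15 (-0.047 and -0.045 without B. thetaiotaomicron replicates 2 and 3), and for Retnlb from -0.049 to 0.0026 (the latter without B. thetaiotaomicron replicate 4). Slc5a8 with E. rectale ran from -0.058 without E. rectale replicate 1 to 0.43, and Muc2 in co-colonized colons from -0.11 to 0.018 without co-colonized replicate 3.

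Between co-colonized and B. thetaiotaomicron colons, Mcpt4 was -0.067 without 2 libraries or without co-colonized replicate 3 and -0.053 without 5 libraries, and ran up to 1.41 with single arrays left out. The T and NK cell list ran from -0.61 to -0.047, the latter without B. thetaiotaomicron replicate 4, with camera's direction turned. With the Hox score, Ccl28 was -0.17, Kit 0.13, Tpsab1 -0.15, Acaa1b 0.099, Acaa2 0.13, and the lists of mast cells -0.10, fatty acid oxidation 0.057 and adipose tissue 0.11. The fatty acid oxidation list between single species was 0.075 without 5 libraries, with camera's direction turned. Intensities near background limit what dim genes can show: the pseudocount of 64 took Gys2 from -0.94 to -0.39.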

Other observations

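The split counts with array weights and for all colonized arrays, and the comparison of all colonized with germ-free arrays, were chosen after other results were seen.

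With arrays weighted by their agreement, 267 genes differed between co-colonized and germ-free colons, 85 higher and 182 lower. Of the 47 glycosylation genes 4 rose and 0 fell, namely B3gnt3 (1.00, SE 0.13, adjusted p = 0.00579), B3galt5 (0.78, SE 0.13), Fut8 (0.56, adjusted p = 0.0433) and St3gal2. The chloride channel regulator gene Clca3b (1.33, SE 0.28) rose, and of 37 absorptive colonocyte genes 1, Phgr1, fell. The growth factor gene Tgfb3 (1.00, SE 0.23), the matrix gene Fbln1 (0.88, SE 0.19) and the phospholipid flippase gene Atp10a (0.70, SE 0.08, adjusted p = 0.00376) rose as well. The hormone gene Cck (-2.91, SE 0.49), the natriuretic peptide clearance receptor gene Npr3 (-1.34, SE 0.19), Apoc3 (-1.32, SE 0.18), Lep (-1.31, SE 0.20), the amylase gene Amy1 (-1.24, SE 0.25), the metallothionein gene Mt2 (-1.16, SE 0.24) and the amino acid transporter gene Slc36a2 (-1.01, SE 0.19) fell. Hoxa13 rose by 2.52 (SE 0.57), from 5.54 ± 1.11 in germ-free to 8.28 ± 0.31 in co-colonized colons without weights (SD, n = 4). Germ-free replicate 2 had the lowest weight, 0.169, and without weights 1 gene was called.

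Across all 12 colonized arrays against the 4 germ-free arrays, Cck was 8.43-fold lower (-3.08, SE 0.49) and Apoc3 2.39-fold lower (-1.26, SE 0.20), each at a limma adjusted p of 0.0608, short of the threshold. Limma called 0 genes, with 2841 at an unadjusted p under 0.05. Acaca (-0.45, SE 0.10), Tmem219 (-0.63, SE 0.13) and the nociceptin precursor gene Pnoc (-0.76, SE 0.16) were lower and Atp10a (0.61, SE 0.13) higher among the 10 smallest p-values, without passing.

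Other splits of the same arrays into groups of equal size were fitted in the same way, and each number of splits below includes the real one. For co-colonized against germ-free, 1 of 35 splits, the real one, reached its 1 called gene (highest other 0). The real split alone also reached its 3364 genes at an unadjusted p under 0.05 (highest other 1935). A share of 1 in 35 is the smallest this test can give, and it was not adjusted over the comparisons made. It speaks against chance for the 3364 genes without excluding it, and a count of 1 against 0 decides nothing. The Hox score differed between these groups, at 1.41 in co-colonized and -0.98 in germ-free colons. The splits therefore cannot tell colonization from sampling position. With array weights 3 of 35 splits reached 267 genes and the highest other called 2580, which points to a structure of the samples, and chance cannot be excluded there. In 1 of those splits, not the real one, the array weights stopped short of their convergence tolerance. For E. rectale against germ-free, 2 of 35 splits reached 1 called gene, and the highest other called 98, which also points to a structure of the samples. At an unadjusted p under 0.05, 6 splits reached 2384 genes (highest other 3675), so chance cannot be excluded for either count. For B. thetaiotaomicron against germ-free, 35 of 35 splits reached 0 called genes (highest other 12) and 8 reached 796 genes at an unadjusted p under 0.05 (highest other 1770). A real count of 0 is reached by every split by construction, here and below, so it tests nothing. Among colonized groups, 35 of 35 splits reached 0 called genes, with highest other counts of 0 for co-colonized against B. thetaiotaomicron, 12 for co-colonized against E. rectale and 6 for B. thetaiotaomicron against E. rectale. At an unadjusted p under 0.05 in the same order, 3 splits reached 974 genes (highest other 1265), 23 reached 689 (highest other 2354) and 4 reached 1654 (highest other 2234). For the interaction, 100 of 100 drawn splits reached 0 called genes (highest other 69) and 92 reached 246 genes at an unadjusted p under 0.05 (highest other 2455). Chance cannot be excluded for any of these counts at an unadjusted p under 0.05, and the counts of 0 decide nothing. For all colonized against germ-free arrays, 100 of 100 drawn splits reached 0 called genes (highest other 161), which again tests nothing. At an unadjusted p under 0.05, 4 of the 100 reached 2841 genes (highest other 3709). That share is under 0.05, but 100 draws are too few to tell it from 0.05, so chance cannot be excluded.

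The real number of lists called by camera was reached in 26 of 35 splits for E. rectale against germ-free (6 lists, highest other 17), 25 for B. thetaiotaomicron against germ-free (7, highest other 18) and 31 for co-colonized against germ-free (5, highest other 15). It was reached in 25 for co-colonized against B. thetaiotaomicron (9, highest other 17), 26 for co-colonized against E. rectale (6, highest other 17), 26 for B. thetaiotaomicron against E. rectale (10, highest other 19) and 95 of 100 for the interaction (4, highest other 20). Chance cannot be excluded for the number of lists in any comparison.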
